A study of Homo sapiens with 12 samples.

How the data were processed

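Poly(A) RNA was measured by RNA sequencing in 12 libraries of human orbital fibroblasts from thyroid eye disease, an autoimmune disorder in which these cells of the eye socket expand the matrix and fat around the eye. The libraries came from 2 fibroblast strains, called strain A and strain B here, each treated with IGF-1 at 50 ng/mL or with vehicle for 24 hours, with 3 libraries per group. Per the labels' protocols, cells grew in medium with 10% serum, were starved in 0.1% serum for 2 days and were treated in that medium, with 0.01% BSA as the vehicle. RNA was extracted with a column kit and libraries were made with a stranded poly(A) kit, per the labels. The submitters call the samples biological replicates. Whether they were separate cultures on separate days is not stated, so p-values measure the spread between these samples, and nothing here separates a strain from its donor.

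The authors deposited 1 table of whole-number read counts per gene symbol, with 1 column for each library. The genome build is hg38, per the submitters' processing notes. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here, so antisense, overlapping and near-identical genes are uncertain. The table held 59428 features, each with a name. Genes annotated only on the Y chromosome and the X-inactivation transcripts, 446 features in all, were left out of every test to protect the donors. Of all features, 29726 had 0 counts in every library. Library totals, numbers of genes with a count and shares of a library's counts were taken with the 446 features included. Library totals ranged from 27814796 to 37456046 counts. Levels are given as CPM, computed from the deposited counts with TMM-adjusted library sizes, and the 95% intervals and the floor of 3 counts used for genes with few counts cover counting error only.

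Counts were tested with edgeR 4.0.16 in R 4.3.3: low counts were removed with filterByExpr by group, libraries were scaled by TMM, and robust quasi-likelihood fits (glmQLFit, glmQLFTest) used 1 mean for each of the 4 groups. This left 15384 genes and a biological coefficient of variation of 10.6%. The contrasts were IGF-1 against vehicle as the mean of the 2 strains, in each strain, the difference of that effect between strains, and strain B against strain A in vehicle. P-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05, and all adjusted p-values for genes below are from edgeR unless another tool is named. Log2 fold changes are given with their standard errors (SE), and CPM as mean ± SD. Agreement between strains was measured as a correlation across genes, which are not independent replicates.

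Gene lists were fixed before the data were examined. There were 36, of which 33 had at least 5 tested members: metabolic, signalling, matrix, immune and stress lists chosen for orbital fibroblasts under IGF-1, and markers of fibroblasts, periocular mesenchyme, endothelium, epithelium, Schwann and neural cells and pericytes. Markers of leukocytes, skeletal muscle and adipocytes had too few tested members. Lists were tested on log2 CPM (prior count 2) with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks only whether a list's genes move one way; p-values were adjusted over lists. Named genes followed a rule fixed at the same time: for the mean of the 2 strains, the 10 largest rises and falls among called genes with a mean of at least 1 CPM and every IGF-1 library beyond every vehicle library of its strain; for each other contrast the 5 largest each way; up to 4 members of each list other than markers by adjusted p; and 14 genes of the IGF-1, hyaluronan, inflammatory and matrix systems whatever their value. Features without a gene symbol or with a clone-based, LOC or LINC name, pseudogenes, HLA genes, immunoglobulin and T cell receptor segments and genes with common whole-gene deletions or null alleles were not named. Some genes that met the rule are not reported here, though counts of results include them. Gene positions are from GENCODE release 29 on GRCh38.

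Alternatives listed before the data were examined were median-ratio scaling, no filter on low counts, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn with the tested genes held fixed, an adjusted p under 0.01, at least a 2-fold change, an additive model and each strain fitted alone. The 5 CPM filter was listed for counts of calls and for agreement, and its use for named genes was added after the data were seen. A length and GC correction was added after a trend was seen: for the 14358 tested genes with a transcript length and GC content (93.33%), a spline surface with 5 degrees of freedom for each property was fitted to each library and passed to edgeR as an offset. Because treatment and this surface move together, the correction can also remove a real effect. The fits were tested on simulated data for the mean of the 2 strains, with 200 genes changed. Without a trend, edgeR recovered 57% of 100 genes changed by 0.5 log2 units and 84% of 100 changed by 1 among 15384 genes, with 7 false calls. With a simulated trend it made 4617 false calls, 96.8% of all calls, and after correction 3 false calls among 14358 genes, with 55.8% of 95 genes and 83.3% of 90 genes recovered. That test favours the correction, since the trend was drawn from the same kind of surface. Of 100 simulated lists with no change, 0 passed camera and 1 had an unadjusted p under 0.05 (with an estimated correlation, 0 passed). Simulated genes were drawn independently of each other, so this does not test the preset correlation for lists whose genes vary together. Among the real lists the estimated correlation was 0.44 for collagens and matrix and 0.79 for mitochondrially encoded transcripts. Figures were drawn with matplotlib 3.10.9.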

Results

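RNA was counted in 12 libraries of orbital fibroblasts, 3 each of strain A and strain B with vehicle and with IGF-1, a growth factor whose receptor is a drug target in thyroid eye disease. The series set out to describe the downstream effects of IGF-1 in these cells. Total counts per library were 30107601 to 33208491 in strain A vehicle, 31968584 to 36111933 in strain A IGF-1, 30600257 to 37456046 in strain B vehicle and 27814796 to 36205049 in strain B IGF-1. Fibroblast markers were abundant, with COL1A2 at 25370 CPM in strain A vehicle and 10200 CPM in strain B vehicle and VIM at 7351 and 4910 CPM. At most 1 of 13 leukocyte markers and at most 2 of 10 skeletal muscle markers reached 1 CPM in any library, and at most 1 of 7 adipocyte markers did. Markers of other cell types were not absent. Up to 6 of 8 pericyte, 6 of 9 Schwann and neural, 5 of 9 epithelial and 5 of 10 endothelial markers reached 1 CPM in a library. Among them KRT14 was at 341 CPM and MBP at 99.2 CPM in strain A vehicle. Other members of these lists were at 0 CPM in that group (KRT5, SOX10, CLDN5 and HIGD1B) or near it (EPCAM at 0.0204 CPM). The markers that reached 1 CPM therefore do not show that such cells were present. Log2 CPM correlated at 0.983 to 0.994 within groups, and library pairs of a group differed by more than sampling noise, with a chi-square per gene of 4.45 to 39.5. The first principal component held 58.5% of the variance and separated the strains, and the second held 27.3% and separated the treatments within each strain.

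**Figure D1:**
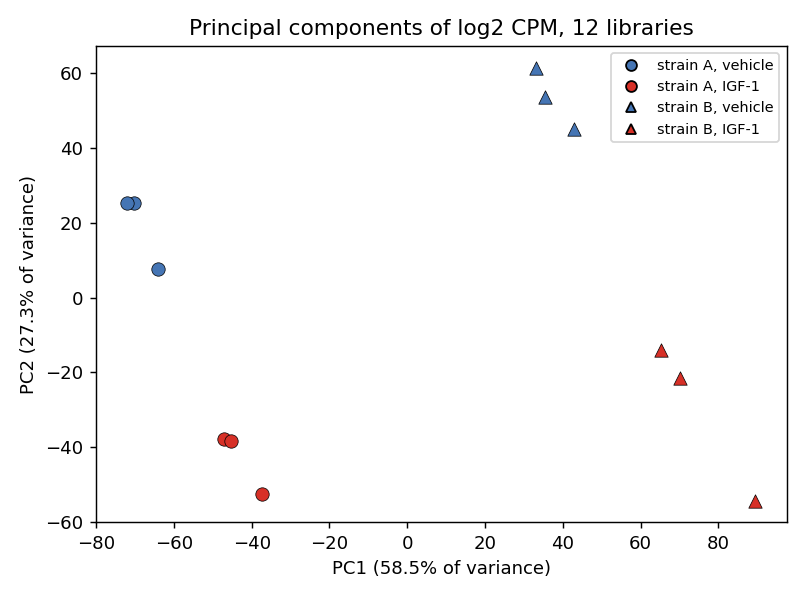
Principal components of log2 CPM for the 12 libraries, with PC1 (58.5% of variance) on the x axis and PC2 (27.3%) on the y axis; circles are strain A, triangles strain B, blue vehicle and red IGF-1. Replicate 3 of strain B with IGF-1 lies at 89.4 and -54.3, apart from the other libraries of its group at 65.2 and -13.9 and at 70.2 and -21.4.

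IGF-1 against vehicle was first compared as the mean of the 2 strains. TUBA1B, an alpha-tubulin (chromosome 12, 49127782 to 49131397), rose from 206 ± 7.70 to 976 ± 48.5 CPM in strain A and from 472 ± 21.9 to 1895 ± 152 CPM in strain B (SD, n = 3). Its log2 fold change was 2.13 (SE 0.05, adjusted p = 2.4e-12). NME1, a nucleoside diphosphate kinase (chromosome 17, 51153536 to 51162428), rose by 2.14 (SE 0.07, adjusted p = 7.62e-11), and RRM2, a subunit of ribonucleotide reductase, by 2.31 (SE 0.16, adjusted p = 2.26e-07). COL1A1, the main chain of type I collagen (chromosome 17, 50183289 to 50201632), fell from 7459 ± 2176 to 1066 ± 440 CPM in strain A and from 1728 ± 632 to 179 ± 110 CPM in strain B (SD, n = 3). The log2 fold change of COL1A1 was -3.04 (SE 0.40, adjusted p = 0.000114). HAS2, a hyaluronan synthase (chromosome 8, 121612116 to 121641390), rose from 33.6 ± 2.91 to 87.7 ± 15.8 CPM in strain A and from 19.0 ± 1.09 to 34.5 ± 3.51 CPM in strain B (SD, n = 3).

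The other largest rises among genes beyond the spread of both strains were ACTG2 at 2.67, EPGN at 2.34, TBXAS1 at 2.31, CDC45 at 2.28, GPD1 at 2.18, UBE2C at 2.11 and TUBB2A at 2.07. The largest falls were HSPG2 (perlecan, chromosome 1, 21822245 to 21937297) at -4.49, BGN (biglycan) at -4.02, AEBP1 at -4.02, COL4A2 at -3.89, TNXB at -3.82, PPL at -3.76, COL6A2 at -3.64, IRS2 at -3.60, FOXP4 at -3.56 and PTPN23 at -3.46. In single libraries counts went down to 0 for FOXP4, 2 for BGN and PTPN23 and 5 for HSPG2. They went down to 6 for ACTG2 and COL4A2 and 7 for PPL and IRS2, so the sizes of these folds depend on few reads. TUBA1B, TUBB2A, NME1, ACTG2 and TNXB have close copies in the genome with which reads can be shared, so their levels are uncertain. In all, 4592 genes rose and 4927 fell of 15384, of which 292 rose and 1382 fell at least 2-fold. Every IGF-1 library lay above every vehicle library of its strain, in both strains, for 3172 genes and below for 3479, where chance gives 0.25% in each direction.

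**Figure D2:**
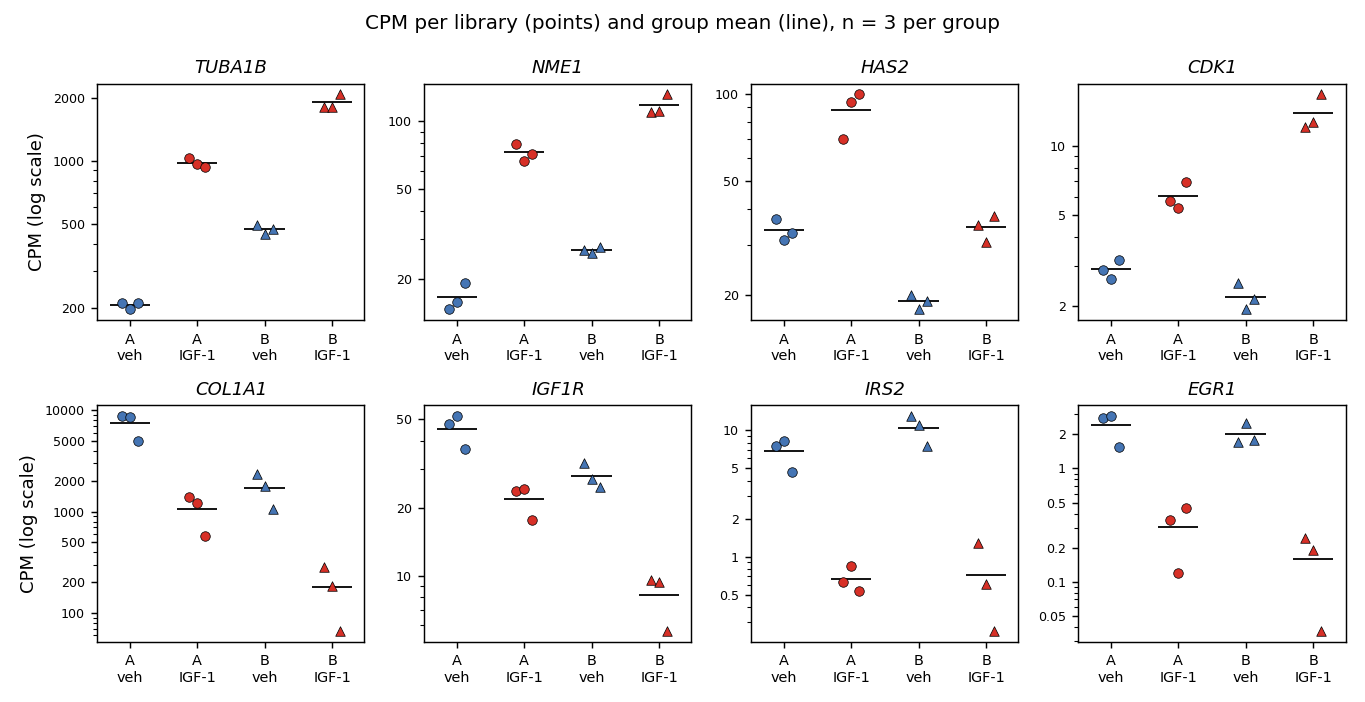
CPM per library on a log axis for 8 genes in the 4 groups (points, n = 3; lines, group means; circles strain A, triangles strain B; blue vehicle, red IGF-1). TUBA1B, NME1, HAS2 and CDK1 were higher with IGF-1 in both strains, and COL1A1, IGF1R, IRS2 and EGR1 were lower.

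The treatments also differed by transcript length and GC content. Among 287 genes with transcripts over 6 kb and a GC content over 55%, the median log2 fold change was -1.25 and 84.3% fell, while for 392 genes of up to 1 kb and 45 to 55% GC the median was 0.32. The mean of 205 long GC-rich genes relative to 464 short ones, in log2 units, was -0.33 ± 0.33 in strain A vehicle, -1.70 ± 0.27 in strain A IGF-1, -0.60 ± 0.30 in strain B vehicle and -2.48 ± 0.61 in strain B IGF-1 (SD, n = 3). Within each of the 4 groups, replicate 3 had the lowest value. Length and GC content together accounted for 28.3% of the variance of the log2 fold changes across genes. After correction for them, 4815 genes rose and 4200 fell of 14358; 6740 calls kept their direction, 386 were called in the opposite direction, 2088 were lost and 1889 were gained. At least 2-fold, 363 genes then rose and 735 fell. COL1A1 fell by 1.82 (SE 0.21), HSPG2 by 2.19, TNXB by 1.51, FOXP4 by 2.37 and BGN by 3.86 after the correction, while TUBA1B rose by 1.88. Mitochondrially encoded transcripts took 1.97% ± 0.222 of counts in strain A vehicle against 1.40% ± 0.161 with IGF-1, and 2.08% ± 0.251 against 1.12% ± 0.0144 in strain B (SD, n = 3).

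**Figure D3:**
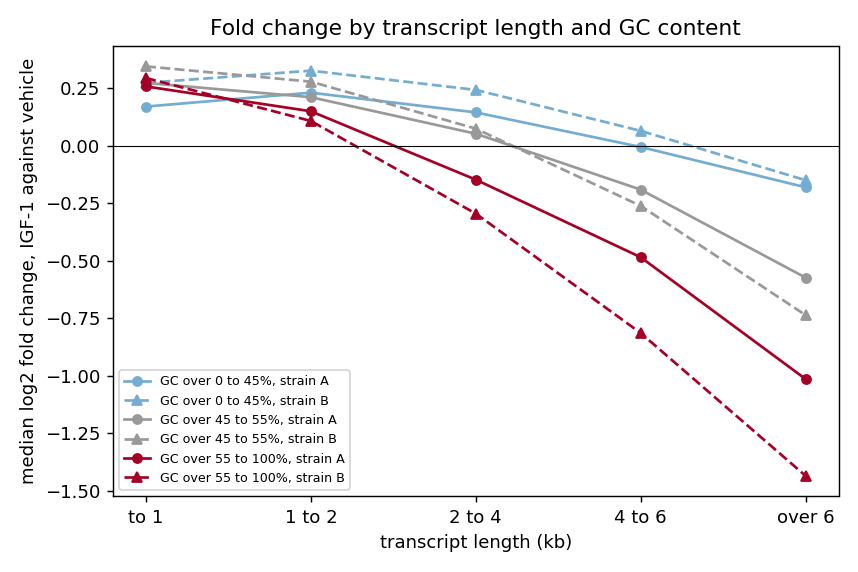
Median log2 fold change of IGF-1 against vehicle by transcript length (x axis, kb) and GC content (colours), for strain A (circles, solid lines) and strain B (triangles, dashed lines). For transcripts over 6 kb with over 55% GC the median was -1.01 in strain A and -1.44 in strain B, against -0.18 and -0.15 for those with up to 45% GC.

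Of the 33 gene lists tested, 10 rose and 15 fell by camera at the preset correlation. With an estimated correlation 0 of 33 passed, 8 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 30. Counts of members below were the same when adjusted over the list alone, except where another number is given.

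Of 25 genes of cholesterol synthesis and uptake, 23 rose and 2 fell, with a median log2 fold change of 0.69 (camera adjusted p = 3.16e-10, adjusted p = 0.0890 with an estimated correlation). HMGCS1, an early enzyme of the pathway, rose by 0.99 (SE 0.05) and ACAT2 by 1.30 (SE 0.06). Of 15 fatty acid synthesis genes 11 rose and 3 fell, with a median of 0.51 (camera adjusted p = 0.00103, adjusted p = 0.203 with an estimated correlation), among them the desaturases FADS2 at 1.18 (SE 0.05) and SCD at 0.79 (SE 0.05). Of 32 genes of the ATF4 and amino acid synthesis list 23 rose and 3 fell (4 fell adjusted over the list alone), with a median of 0.47 (camera adjusted p = 1.43e-06, adjusted p = 0.0890 with an estimated correlation). PSPH of serine synthesis rose by 1.26 and PYCR1 of proline synthesis by 1.19. Of 29 glycolysis and hypoxia genes 15 rose and 7 fell, with a median of 0.24 (camera adjusted p = 0.0286, adjusted p = 0.251 with an estimated correlation). TPI1 rose by 1.05. Nuclear genes of oxidative phosphorylation rose in 27 of 28 cases, with a median of 0.53 (camera adjusted p = 3.16e-10, adjusted p = 0.243 with an estimated correlation). With the length and GC correction 24 of these rose, with a median of 0.31. In contrast 12 of 13 mitochondrially encoded transcripts fell (13 adjusted over the list alone), with a median of -0.88 (camera adjusted p = 3.2e-05, adjusted p = 0.281 with an estimated correlation).

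Cell cycle genes rose in 23 of 30 cases and 1 fell, with a median of 0.80 (camera adjusted p = 1.38e-06, adjusted p = 0.119 with an estimated correlation). CDK1, the kinase of mitotic entry, rose by 1.85 (SE 0.12) and BIRC5 by 2.03 (SE 0.15). Of 28 genes of ribosome biogenesis and MYC targets 14 rose and 6 fell (15 rose adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.0276, adjusted p = 0.203 with an estimated correlation). ODC1 rose by 1.10. Of 21 genes of the unfolded protein response 12 rose and 4 fell, with a median of 0.32 (camera adjusted p = 0.00689, adjusted p = 0.186 with an estimated correlation). HSPA5 rose by 0.70. Both of these list calls ended after the length and GC correction, with a camera adjusted p of 0.0729 and 0.0618 and medians of 0.21 and 0.19. NRF2 and oxidative stress genes rose in 13 of 22 cases and 1 fell, with a median of 0.45 (camera adjusted p = 0.000381, adjusted p = 0.2497 with an estimated correlation). NQO1 rose by 1.10. Interferon response genes rose in 19 of 26 cases and 1 fell, with a median of 0.53 (camera adjusted p = 4.82e-05, adjusted p = 0.290 with an estimated correlation). OAS1 rose by 0.92. Of 18 p53 target and senescence genes 10 rose and 4 fell, with a median of 0.16, which did not pass camera (adjusted p = 0.149).

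FOXO target genes, which insulin-like signals repress, fell in 20 of 24 cases and 3 rose, with a median of -0.83 (camera adjusted p = 3.93e-06, adjusted p = 0.0890 with an estimated correlation). PDK4 fell by 2.35 (SE 0.15) and FBXO32 by 1.27 (SE 0.05), with PDK4 also on the glucocorticoid list. Of 25 genes of MAPK feedback and early response 19 fell and 1 rose (20 fell adjusted over the list alone), with a median of -0.60 (camera adjusted p = 0.000122, adjusted p = 0.118 with an estimated correlation). EGR1 fell by 3.27 (SE 0.30), with 1 to 86 counts per library, so the size of this fold depends on few reads. Of 22 IGF system genes 13 fell and 4 rose, with a median of -0.54 (camera adjusted p = 0.00505, adjusted p = 0.315 with an estimated correlation). After the length and GC correction its median was -0.19 and the camera adjusted p was 0.0729. IGF1R, the receptor of IGF-1 (chromosome 15, 98648539 to 98964530), went from 45.3 ± 7.61 to 21.97 ± 3.69 CPM in strain A and from 27.9 ± 3.55 to 8.19 ± 2.21 CPM in strain B (SD, n = 3). The log2 fold change of IGF1R was -1.40 (SE 0.14, adjusted p = 4.52e-06) and became -0.39 after the correction. The log2 fold change of INSR was -1.74 (-1.03 after the correction), that of IRS1 -1.01 (-0.18 after it) and that of IRS2 -3.60 (-2.29 after it). IGF1 had a log2 fold change of -0.40 (SE 0.19, adjusted p = 0.0880), which passed with the replicate number as a block (adjusted p = 0.0280), without strain A vehicle replicate 1 (0.0445) and without strain A IGF-1 replicate 3 (0.0321). Its log2 fold change was 0.08 in strain A (SE 0.24, adjusted p = 0.812) and -0.87 in strain B (SE 0.30, adjusted p = 0.0252), a difference that did not pass (adjusted p = 0.247). STC2 fell by 0.56, and its call ended after the correction (-0.11, adjusted p = 0.0604).

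Of 40 collagen and matrix genes 29 fell and 7 rose, with a median of -1.18 (camera adjusted p = 0.00026, adjusted p = 0.359 with an estimated correlation), and after the length and GC correction 23 fell and 7 rose, with a median of -0.62. SERPINH1, a collagen chaperone, rose by 0.82 and LOXL3 by 0.87, while LOX fell by 0.57. Of 16 TGF-beta target genes 12 fell and 2 rose, with a median of -0.41 (camera adjusted p = 0.00345, adjusted p = 0.235 with an estimated correlation). CCN2 fell by 1.96 (SE 0.07). Of 21 matrix proteases and inhibitors 14 fell and 5 rose, with a median of -0.50 (camera adjusted p = 0.0156, adjusted p = 0.352 with an estimated correlation). ADAMTS1 fell by 1.00 while TIMP4 rose by 1.32. Contractile and myofibroblast genes rose in 5 and fell in 8 of 15 cases, with a median of -0.15 (0.01 after the correction) that did not pass camera (adjusted p = 0.468). ACTA2, smooth muscle actin, had a log2 fold change of -0.15 (SE 0.06, adjusted p = 0.0417), a call that ended with median-ratio scaling (0.0540), with DESeq2 (0.0659) and in each of 8 fits without 1 library (highest adjusted p 0.147, without strain A IGF-1 replicate 2). After the length and GC correction ACTA2 fell by 0.47.

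Hyaluronan metabolism did not pass as a list (8 of 17 rose and 5 fell, 6 adjusted over the list alone, median 0.09, -0.04 after the length and GC correction, camera adjusted p = 0.534). Among the synthases HAS2 rose by 1.12 (SE 0.09, adjusted p = 1.05e-07) and HAS1 by 1.20 (SE 0.22, adjusted p = 0.000209). Counts per library were 590 to 3571 for HAS2 and only 7 to 58 for HAS1. HAS3 had a log2 fold change of -0.75 (SE 0.26, adjusted p = 0.0227), which did not pass after the correction (-0.49, adjusted p = 0.158) or in 5 fits without 1 library (highest 0.0610, without strain B IGF-1 replicate 2). It was at -0.20 in strain A (adjusted p = 0.693) and -1.30 in strain B (adjusted p = 0.00816), and this difference did not pass (adjusted p = 0.342). CEMIP, which takes part in hyaluronan breakdown, fell by 2.30 (log2 fold change -1.499 after the correction) and CD44, a hyaluronan receptor, by 0.71 (-0.45 after it). Of 18 thyroid eye disease receptors and antigens 15 fell and 1 rose, with a median of -0.56 and of -0.36 after the correction (camera adjusted p = 0.000366 before it, adjusted p = 0.235 with an estimated correlation). TSHR, the thyrotropin receptor, had 0 to 9 counts per library and was not tested. Adipogenesis and lipid storage did not pass as a list (4 of 17 rose, 9 fell, median -0.39, -0.23 after the correction, camera adjusted p = 0.140), and PPARG rose by 0.40 (SE 0.06, adjusted p = 2.98e-05, 0.16 after the correction) and FABP5 by 1.76.

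Complement genes fell in 13 of 16 cases and 1 rose, with a median of -1.09 (camera adjusted p = 7.72e-05, adjusted p = 0.235 with an estimated correlation). CFD fell by 1.36. Cytokines, chemokines and NF-kB did not pass (9 of 32 rose, 14 fell, median -0.22, camera adjusted p = 0.507), but passed downward after the correction (adjusted p = 0.0225, adjusted p = 0.394 with an estimated correlation). IL6 fell by 0.40 (SE 0.12, adjusted p = 0.0079, and -0.68 after the correction). CXCL8 was at 0.11 (SE 0.15, adjusted p = 0.542), at -0.16 after the correction and at -0.07 without strain B IGF-1 replicate 3, and passed in none of these 3 fits. Lysosome and autophagy genes fell in 18 of 26 cases and 4 rose (5 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 0.00196, adjusted p = 0.119 with an estimated correlation). CTSD fell by 1.66. Wnt target genes fell in 11 of 15 cases and 1 rose, with a median of -0.54 (camera adjusted p = 0.00379, adjusted p = 0.235 with an estimated correlation). After the correction the median was -0.23. DKK1 fell by 0.89. Members of this list such as DKK1 and SFRP2 are secreted Wnt inhibitors, so its fall does not show lower Wnt signalling. Glucocorticoid response genes fell in 10 of 12 cases and 2 rose, with a median of -0.43 (camera adjusted p = 0.00345, adjusted p = 0.0890 with an estimated correlation). MT2A fell by 0.96 while TSC22D3 rose by 0.95.

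Among cell type markers, 11 of 14 fibroblast genes fell and 3 rose, with a median of -0.78 (camera adjusted p = 0.00398, adjusted p = 0.290 with an estimated correlation) and of -0.45 after the correction. Periocular mesenchyme markers fell in 6 of 11 cases and 1 rose (camera adjusted p = 0.0382, adjusted p = 0.281 with an estimated correlation). Endothelial markers fell in 6 of 7 (camera adjusted p = 0.0276, adjusted p = 0.235 with an estimated correlation). Both calls ended after the correction (adjusted p = 0.0618 and 0.208), and that of periocular mesenchyme markers also without strain B IGF-1 replicate 1 (adjusted p = 0.0506). Pericyte markers (5 of 7 fell, 1 rose, camera adjusted p = 0.0536) passed with the replicate block (adjusted p = 0.0408) and in 5 fits without 1 library, from 0.0431 without strain A IGF-1 replicate 2 to 0.0496 without strain A vehicle replicate 3. With all libraries and no block their adjusted p was 0.210 with an estimated correlation. Epithelial markers (1 rose and 1 fell of 6, adjusted p = 0.863) and Schwann and neural markers (3 rose, 4 adjusted over the list alone, and 2 fell of 7, adjusted p = 0.377) did not pass camera.

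**Figure D4:**
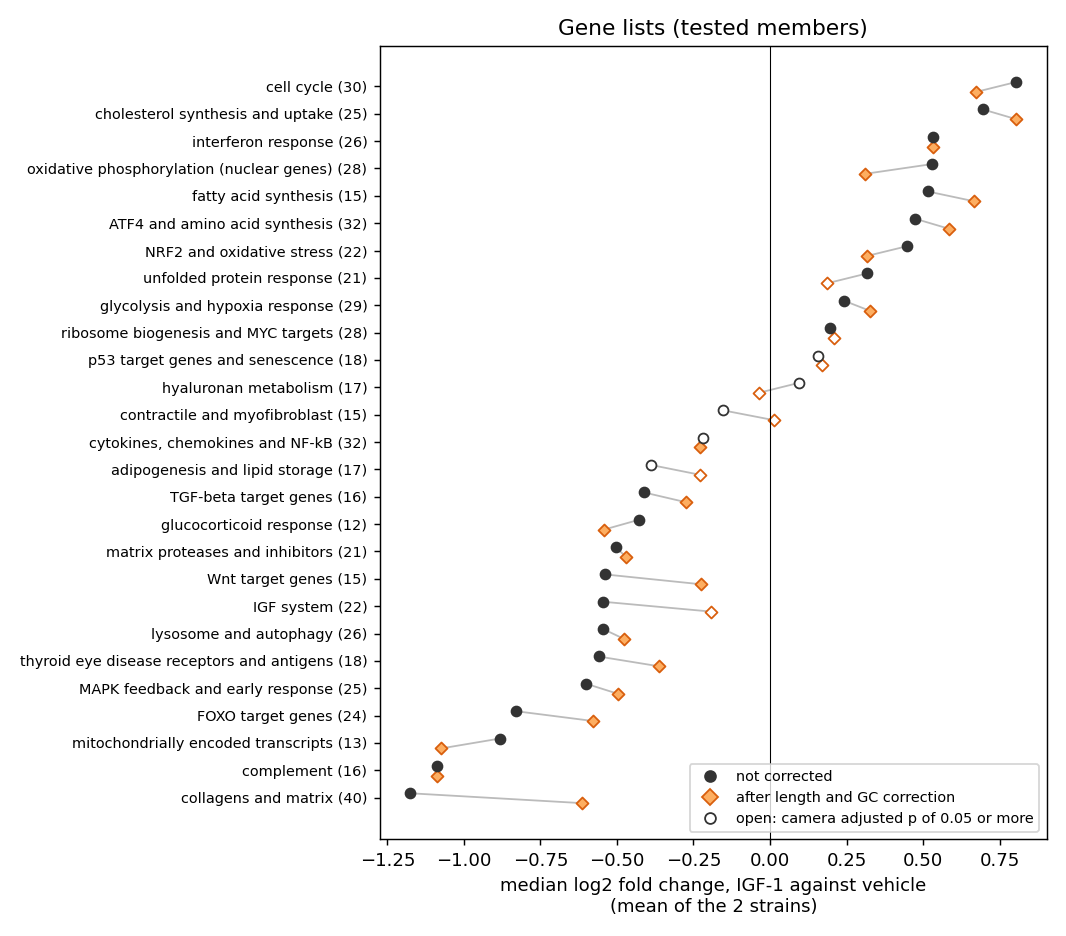
Median log2 fold change (x axis) of each tested gene list other than cell type markers for IGF-1 against vehicle, mean of the 2 strains. Circles are without correction and diamonds after the length and GC correction, with open symbols for a camera adjusted p of 0.05 or more. The collagen and matrix list moves from -1.18 to -0.62 and the cholesterol list from 0.69 to 0.80.

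Within strain A, IGF-1 raised SLCO4C1, a transporter, by 2.72 (SE 0.43), GPD1 by 2.61, ACTG2 by 2.54, TBXAS1 by 2.38 and TUBA1B by 2.25. In strain A vehicle SLCO4C1 was at 0.101 to 0.135 CPM and ACTG2 at 0.183 to 0.236 CPM. Their counts went down to 3 and 6 in single libraries, so the sizes of their folds depend on few reads. The largest falls were TNXB (tenascin-X) at -4.45 (SE 0.58), HSPG2 at -4.08, LRP1 at -3.81, GALNT15 at -3.71 (SE 0.12) and SSC5D at -3.63. SSC5D went down to 5 counts in single libraries, so the size of its fold also depends on few reads. After the length and GC correction TNXB was at -2.24, HSPG2 at -1.89, LRP1 at -2.04 and GALNT15 at -3.53. In this strain 3244 genes rose and 3458 fell, and 264 rose and 1060 fell at least 2-fold. After the correction more genes rose than fell, 3613 against 3130, and 288 rose and 603 fell at least 2-fold. Of the 33 lists 9 rose and 12 fell by camera, and 4 passed with an estimated correlation, namely cholesterol synthesis, FOXO targets and ATF4 (each adjusted p = 0.0450 with an estimated correlation) and the unfolded protein response (adjusted p = 0.0480 with an estimated correlation). With the length and GC correction none of these 4 passed in that way (adjusted p = 0.0776, 0.0726, 0.164 and 0.102 with an estimated correlation, in that order), and fatty acid synthesis did (adjusted p = 0.0477 with an estimated correlation).

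Within strain B, CDC45, a DNA replication factor, rose by 2.98 (SE 0.21), RRM2 by 2.97 (SE 0.23), ACTG2 by 2.79, BIRC5 by 2.76 and EPGN by 2.70. Cell cycle genes as a list rose in 26 of 30 cases and 1 fell (27 rose adjusted over the list alone), with a median of 1.11 (camera adjusted p = 7.51e-10, adjusted p = 0.0995 with an estimated correlation). The largest falls were BGN at -4.95 (SE 0.61), HSPG2 at -4.89, COL4A2 at -4.49, AEBP1 at -4.43 and COL6A2 at -4.11. Corrected for length and GC content, BGN was at -4.70, HSPG2 at -2.49, COL4A2 at -2.97, AEBP1 at -3.57 and COL6A2 at -3.16. In this strain 4060 genes rose and 4404 fell, and 435 rose and 1740 fell at least 2-fold. After the correction more genes rose than fell, 4455 against 3573, and 525 rose and 924 fell at least 2-fold. Of the 33 lists 9 rose and 16 fell by camera, while 0 passed with an estimated correlation, 9 had an unadjusted p under 0.05 and fry called 28. For hyaluronan metabolism (median 0.03, mean -0.04) and p53 targets (median 0.06, mean -0.03), which did not pass, median and mean differed in sign. Replicate 3 with IGF-1 in this strain had counts for 19408 genes against 21339 and 21667 in the other libraries of its group, and 1429 genes with a single count against 2448 and 2612. It also had the lowest total of all libraries, 27814796 counts. At that depth the other libraries of its group would be expected to have counts for 20949 and 20980 genes, so depth accounts for part of the gap. Without replicate 3 with IGF-1, 3638 genes rose and 4022 fell in strain B.

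The effects in the 2 strains correlated across 15384 genes at r = 0.77 (Spearman rho = 0.78). TUBA1B, NME1 and HAS2 rose and COL1A1, IGF1R and PDK4 fell in both strains. Of the called genes 2664 rose in both, where independent lists give 856, 2843 fell in both, where independent lists give 990, and 64 were called in opposite directions. The strains share no library. After the length and GC correction r was 0.73. With no filter on low counts r was 0.20 over 29681 genes.

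**Figure D5:**
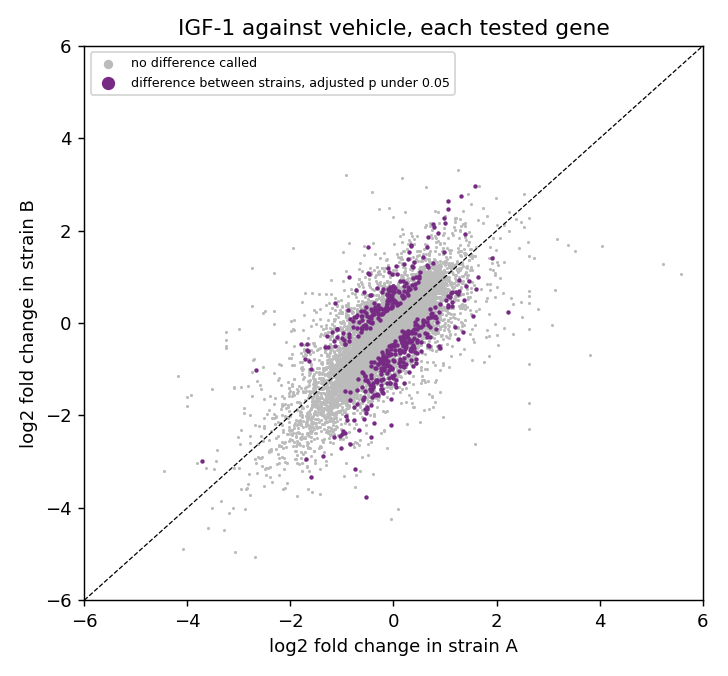
Log2 fold change of IGF-1 against vehicle in strain A (x axis) and strain B (y axis) for each of 15384 tested genes; purple points have a difference between strains at an adjusted p under 0.05 and the dashed line marks equal effects. The correlation across genes was 0.77.

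The difference of the IGF-1 effect between strains was tested for each gene. CDK1 rose more in strain B, from 2.20 ± 0.30 to 13.9 ± 2.54 CPM, than in strain A, from 2.90 ± 0.28 to 6.03 ± 0.84 CPM (SD, n = 3), a difference of 1.59 log2 units (SE 0.23, adjusted p = 0.00211). Cell cycle genes as a list rose more in strain B, with a median difference of 0.70 and 8 of 30 genes called (18 adjusted over the list alone; camera adjusted p = 3.23e-17, adjusted p = 0.0514 with an estimated correlation). Cholesterol synthesis genes rose more in strain A on the log2 scale, with a median difference of -0.50 and 12 of 25 called (19 adjusted over the list alone; camera adjusted p = 4.04e-16, adjusted p = 0.0514 with an estimated correlation), HMGCS1 among them at -0.57. These rises are relative to unequal starting levels, since 24 of the 25 genes were higher in strain B than in strain A in vehicle. RIPOR2 fell by 2.66 in strain A and 1.02 in strain B (difference 1.64, SE 0.25). TMEM37 rose by 2.23 in strain A and was at 0.23 in strain B (difference -2.00, SE 0.44, adjusted p = 0.0242), a call that ended with limma-voom (0.0577). NANOS1 was at -0.04 in strain A and fell by 2.21 in strain B, and the call of this difference also ended with limma-voom (0.0741). Counts went down to 6 for TMEM37 and 3 for NANOS1 in single libraries, so the sizes of both differences depend on few reads.

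In all, the effect was more positive in strain B for 187 genes and more negative for 273. This count rose to 908 after the length and GC correction, 1211 with the replicate block, 1136 with no filter and 721 with DESeq2, with 470 more positive and 438 more negative after the correction. Leaving out single libraries gave 201 to 576, with 255, 254 and 272 without strain A vehicle replicates 1, 2 and 3, 289 without strain A IGF-1 replicate 2, 201 and 283 without strain B vehicle replicates 2 and 3, and 283 without strain B IGF-1 replicate 2. Of the 33 lists 3 were more positive and 11 more negative in strain B by camera, and 0 passed with an estimated correlation, where 7 had an unadjusted p under 0.05 and fry called 7. Among lists that did not pass, median and test differed in sign for MAPK feedback (median -0.03, with fry also downward), TGF-beta targets (-0.11), interferon response (-0.06) and glycolysis (0.003378 with a test downward), and median and mean for periocular mesenchyme markers (-0.28 and 0.01) and glucocorticoid response (0.02 and -0.07).

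Without IGF-1 the strains differed in immune and matrix genes. Of 26 interferon response genes all 26 were higher in strain B, with a median of 2.33 (camera adjusted p = 1.14e-19, adjusted p = 0.128 with an estimated correlation), as OASL at 142 ± 24.6 against 4.97 ± 1.58 CPM (SD, n = 3). Of 32 cytokine, chemokine and NF-kB genes 28 were higher and 2 lower (29 higher adjusted over the list alone), with a median of 1.40 (camera adjusted p = 7.09e-14, adjusted p = 0.128 with an estimated correlation), IL6 by 1.88 and CXCL8 by 1.68. Cholesterol synthesis genes were higher in 24 of 25 cases (median 1.20, camera adjusted p = 8.8e-17, adjusted p = 0.0913 with an estimated correlation). Collagen and matrix genes were lower in 28 of 40 (29 adjusted over the list alone; median -0.91, camera adjusted p = 3.24e-09, adjusted p = 0.397 with an estimated correlation).

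Among single genes PSG4, a pregnancy-specific glycoprotein, was at 205 ± 12.7 CPM in strain B and 0.174 ± 0.0855 CPM in strain A vehicle (SD, n = 3); it belongs to a family of near-identical genes, so its level is uncertain. PLPP2 was higher in strain B by 8.69 log2 units and PNLIPRP3 by 7.61, with 5 and 9 counts in strain A vehicle. Their 95% counting intervals were 197 to 1420 times and 111 to 461 times. GRID1 had 722 counts in strain B and 0 in strain A, 225.7-fold higher against a floor of 3 counts over the group. The lower end of its 95% counting interval was 183.1-fold. APOL4 was 155 times higher (95% counting interval 42.6 to 1287, 2 counts in strain A). KRT14, a keratin on the epithelial marker list, was lower in strain B, at 4.80 ± 0.793 against 341 ± 22.5 CPM (SD, n = 3), a log2 difference of -6.15 (SE 0.15). HAPLN1 was at -7.24, with 5 counts in strain B vehicle (95% counting interval 66.6 to 482 times higher in strain A). LERFS was 239 times higher in strain A (65.7 to 1978), ROBO2 191 times (33.8 to 7581) and OSTN 114 times (31.1 to 943.8), with 2, 1 and 2 counts in strain B. Of the 33 lists 7 were higher and 3 lower in strain B by camera, 0 passed with an estimated correlation, 5 had an unadjusted p under 0.05 and fry called 23. Median and mean differed in sign for periocular mesenchyme markers (-0.19 and 0.21), which did not pass, and fry was upward for these, hyaluronan metabolism and glucocorticoid response against a downward camera test. In all 3517 genes were higher and 3143 lower in strain B, while after the length and GC correction 3556 were higher and 3876 lower. With 1 strain on each side, these differences describe these strains and no wider group.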

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

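Some tests of the results flagged here were chosen only after the result was seen. They were the test of a length and GC bias between libraries, the length and GC correction, the grouping of splits by the orientation of the treatments, and the comparison of the length and GC contrast by replicate number.

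Long, GC-rich transcripts were lower in IGF-1 libraries relative to short ones, with a difference of -1.37 log2 units in strain A and -1.88 in strain B. Leaving the 50 most abundant genes out of the library sizes kept 99.3% of this contrast, but library size cancels between genes of 1 library, so that test decides nothing about a few genes taking most of the counts. The largest range within a group was 0.61 of the treatment difference of its strain, so libraries treated alike also differ along this axis, and replicate 3 had the lowest value in all 4 groups, where chance gives 3.7% for some number. A length and GC bias between libraries cannot be told apart from an effect of IGF-1 on such transcripts, because every vehicle library lies on one side of the IGF-1 libraries of its strain. An effect of IGF-1 stays open and was not tested separately.

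Collagen and matrix genes were lower in IGF-1 libraries, with a list median of -1.18. After the length and GC correction the median was -0.615 (camera adjusted p = 0.00166, adjusted p = 0.3575 with an estimated correlation). The bootstrap 95% interval of this median was -1.05 to -0.215. It was drawn over list members as if independent, though their estimated correlation before the correction was 0.44. It therefore does not measure the spread between libraries. Only at the preset correlation does the remaining fall argue against the trend as the whole cause. That the trend accounts for part of the fall stays open. With an estimated correlation the uncorrected list had an adjusted p of 0.359, so the comparison with other genes rests on the preset correlation.

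Cell cycle genes rose more in strain B, with a median difference of 0.6972 (camera adjusted p = 3.227e-17, adjusted p = 0.0514 with an estimated correlation). Without the third IGF-1 library of strain B the median difference was 0.647 (0.502 to 0.977, adjusted p = 1.97e-17), and after the length and GC correction it was 0.656 (0.524 to 1.07, adjusted p = 5.7e-15, adjusted p = 0.0722 with an estimated correlation). The median difference stayed without that library and after the correction, which argues against that library alone or the trend as the whole cause. Both intervals were drawn over list members as if independent (estimated correlation 0.13), so they do not measure the spread between libraries. With an estimated correlation the list did not pass before or after the correction, and the fit without that library was not tested in that way. A different response of the strains is a candidate explanation, found and tested on the same libraries and with only 1 strain on each side.

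A difference between strains in the edgeR test of the IGF-1 effect, strain B minus strain A, also marked RIPOR2 (1.638, adjusted p = 0.00262), CDK1 (1.588, 0.00211), CEP72 (1.57, 0.0237), TINAGL1 (1.567, 0.0254) and ORC1 (1.552, 0.0296). In the other direction it marked NANOS1 (-2.165, 0.0451), PLXNA4 (-2.033, 0.0155), TMEM37 (-1.996, 0.0242) and BCAM (-1.798, 0.0181). Leaving out 1 library ended the call of NANOS1 in 9 fits (highest adjusted p 0.142, without strain B IGF-1 replicate 2), ORC1 in 7 (0.0817, without strain A vehicle replicate 1) and TMEM37 in 7 (0.0849, without strain A vehicle replicate 3). It also ended that of CEP72 in 6 (0.0740, without strain A vehicle replicate 1), TINAGL1 in 5 (0.0762, without strain A vehicle replicate 2) and BCAM in 2 (0.0570, without strain B vehicle replicate 2).

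By the camera test of the same difference, several lists were more negative in strain B. They were cholesterol synthesis (-0.4999, adjusted p = 4.043e-16, adjusted p = 0.0514 with an estimated correlation) and fatty acid synthesis (-0.4799, 3.024e-05, adjusted p = 0.135 with an estimated correlation). So were collagens and matrix (-0.4686, 0.0002675, adjusted p = 0.632 with an estimated correlation), complement (-0.3423, 0.002356, adjusted p = 0.484 with an estimated correlation) and the IGF system (-0.3247, 0.01164, adjusted p = 0.632 with an estimated correlation). The direction was shared by matrix proteases (-0.5231, 5.629e-05, adjusted p = 0.339 with an estimated correlation), lysosome and autophagy (-0.2663, 0.0002744, adjusted p = 0.109 with an estimated correlation) and the unfolded protein response (-0.1113, 0.006777, adjusted p = 0.166 with an estimated correlation). It was also shared by mitochondrially encoded transcripts (-0.389, 0.004767, adjusted p = 0.636 with an estimated correlation), fibroblast markers (-0.4213, 0.0008528, adjusted p = 0.420 with an estimated correlation) and pericyte markers (-0.7729, 0.01164, adjusted p = 0.135 with an estimated correlation). More positive in strain B were ATF4 and amino acid synthesis (0.1711, 0.0009014, adjusted p = 0.155 with an estimated correlation) and nuclear genes of oxidative phosphorylation (0.09453, 0.007206, adjusted p = 0.718 with an estimated correlation). After the length and GC correction the IGF system (camera adjusted p = 0.0817) and oxidative phosphorylation (0.220) no longer passed, and epithelial markers did (0.0390, adjusted p = 0.332 with an estimated correlation). The median difference was then -0.32 for fatty acid synthesis, -0.24 for collagens and matrix, -0.19 for the IGF system and -0.27 for fibroblast markers. Leaving out 1 library ended the call of the IGF system in 4 fits (highest adjusted p 0.135, without strain B vehicle replicate 1), of oxidative phosphorylation in 4 (0.345, without strain B IGF-1 replicate 3) and of mitochondrially encoded transcripts in 3 (0.0802, without strain B vehicle replicate 1). It also brought calls of epithelial markers in 5 fits (lowest adjusted p 0.0224, without strain A IGF-1 replicate 1) and of p53 targets in 4 (0.0183, without strain B IGF-1 replicate 3). With all libraries these lists had an adjusted p of 0.420 and 0.397 with an estimated correlation. In 1 fit each it brought calls of cytokines (0.0183) and ribosome biogenesis (0.0336), both without strain B IGF-1 replicate 3, interferon response (0.0214, without strain B vehicle replicate 3) and periocular mesenchyme markers (0.0393, without strain A IGF-1 replicate 3). With all libraries these 4 lists had, in that order, an adjusted p of 0.925, 0.484, 0.927 and 0.636 with an estimated correlation.

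For the mean of the 2 strains, 1 of 100 splits of the libraries, the real one, gave as many calls (9519, highest other 5934), so chance is excluded at that level. Strain A (6702 calls, highest other 0), strain B (8464, highest other 0) and the strain comparison (6660, highest other 0) allow only 10 splits, 1 of which gave as many, too few for a share under 0.05. For the difference between strains, 6 of 100 splits gave at least the 460 calls, with a highest other count of 9519, so chance is not excluded by this count. In all 5 others the treatments were opposed in 1 strain, which makes them contrast IGF-1 with vehicle, a structure of the samples; among 41 splits not opposed in this way the highest count was 23.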

How the results depend on the processing

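The length and GC correction and the strict filter for named genes were chosen after the data were seen. Of the 171 results for named genes, 170 held with median-ratio scaling and with DESeq2, 169 with limma-voom and with the correction, 171 with no filter, and 145 of 145 with the strict filter; with 1 library left out 2001 held, 49 lost a call and 2 gained one. With the replicate block 160 held and 1 gained a call. A result held if it kept its call or stayed uncalled. Most named genes were picked from these data for large folds or small adjusted p, so these numbers do not measure how calls of all genes hold. Among all genes with a length and GC content, 2088 calls for the mean were lost after the correction. No called named gene, and no called list for the mean or the difference, turned direction in the alternatives run for it, although 386 of the genes called for the mean were called in the opposite direction after the correction. The balance of calls did turn after the correction: 53.4% were upward for the mean (48.2% without it), 53.6% in strain A (48.4%), 55.5% in strain B (47.97%), 51.8% for the difference (40.7%) and 47.85% for strain B against strain A (52.8%). With it CXCL8 also turned sign. For the difference, the camera direction of the glycolysis, adipogenesis and NRF2 lists turned, as did the median of the adipogenesis, hyaluronan, TGF-beta, MAPK and thyroid eye disease lists. None of these passed before or after. The cause of changed counts was not tested, except that stricter thresholds call fewer genes by construction.

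At least a 2-fold change left 1674 genes for the mean of the 2 strains, 1324 in strain A and 2175 in strain B, and an adjusted p under 0.01 left 4380 in strain A and 150 for the difference between strains. The difference gave 1136 genes with no filter, 721 with DESeq2, 1211 with the replicate block and 908 with the length and GC correction. Agreement between strains was 0.2019 with no filter (29681 genes) and 0.8939 with the strict filter (10437 genes). With an estimated correlation 0 lists passed for the mean (8 at an unadjusted p under 0.05, 30 with fry) and 0 for the difference (7 unadjusted), for which fry gave 7.

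Leaving out 1 library gave 8954 to 9639 genes for the mean, 5175 to 7580 in strain A, 7232 to 8812 in strain B, 201 to 576 for the difference, 5622 to 7470 between strains, an agreement of 0.7298 to 0.7726, 24 to 26 lists for the mean and 12 to 16 for the difference. With the low-count filter run again each time, the difference gave 199 to 573 genes and agreement was 0.7047 to 0.7484.

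Same-numbered libraries had correlated deviations of 0.102, 0.118 and 0.236 in strain A and 0.223, 0.0292 and 0.270 in strain B; 1 of the 6 was under 0.1, so the numbers were not taken as pairs, although 5 of 6 correlated best with their own number. With the replicate block 9881 genes were called for the mean, 7540 in strain A, 8952 in strain B and 1211 for the difference, with 26 lists for the mean, 15 for the difference and an agreement of 0.7713. With the block, IGF1 (adjusted p = 0.0280), pericyte markers for the mean (0.0408) and epithelial markers for the difference (0.0421) passed, and no other call of a named gene or list changed. Without the block these lists had an adjusted p of 0.210 and 0.420 with an estimated correlation. The strain comparison has no fit with the block. Other pseudocounts, listed for the gene tests in case the table held normalized values, were not run because it holds counts, and the prior count of 2 behind the log2 CPM of the list tests was not varied. TSHR, at 0 to 9 counts per library, was not tested, and whether depth or low expression sets this was not examined.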

Other observations

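The length and GC correction was chosen after the data were seen. In vehicle, ATF4 and amino acid synthesis genes were lower in strain B in 21 of 32 cases and higher in 3 (22 lower adjusted over the list alone), with a median of -0.51 (camera adjusted p = 3.511e-06, adjusted p = 0.111 with an estimated correlation). Fatty acid synthesis genes were higher in 12 of 15 (median 0.71, camera adjusted p = 4.148e-06, adjusted p = 0.128 with an estimated correlation). NRF2 and oxidative stress genes were higher in 12 of 22 cases and lower in 3 (14 higher adjusted over the list alone; median 0.36, camera adjusted p = 0.00261, adjusted p = 0.483 with an estimated correlation). Glycolysis genes were higher in 15 of 29 and lower in 4 (median 0.26, camera adjusted p = 0.0276, adjusted p = 0.397 with an estimated correlation). Nuclear oxidative phosphorylation genes were higher in 12 of 28 and lower in 1 (median 0.21, camera adjusted p = 0.0374, adjusted p = 0.781 with an estimated correlation). That call ended after the length and GC correction (median 0.13, adjusted p = 0.0821). Fibroblast markers were lower in strain B in 11 of 14 cases and higher in 1, with a median of -0.78 (camera adjusted p = 0.000213, adjusted p = 0.397 with an estimated correlation).

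SFRP2, a secreted Wnt inhibitor, was at 878 ± 36.6 CPM in strain B vehicle and 92.6 ± 7.64 CPM in strain A vehicle (SD, n = 3), and fell with IGF-1 by 0.64. CCL8, a chemokine, rose by 1.48 with IGF-1 and IL16 fell by 2.46 (log2 fold change -1.58 after the correction), while the cytokine list as a whole did not pass. FABP5 rose by 1.06 in strain A and 2.46 in strain B, a difference of 1.40 (SE 0.23, adjusted p = 0.00485). MYC itself fell by 0.62 with IGF-1, while NOP16 and WDR12 of the ribosome biogenesis and MYC target list rose by 0.80 (0.47 after the correction) and 0.57.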
